A study of Mus musculus with 24 samples.

How the data were processed

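Total RNA was sequenced from the hippocampus of mouse pups that had undergone hypoxia-ischemia, a model of perinatal brain injury, on postnatal day 10, per the labels. The 24 libraries fell into 12 groups of 2, given by genotype (wild type, labelled Neil1-KO, or Neil2-KO), side of the brain (contralateral or ipsilateral to the injury) and time after the insult (3 h or 6 h), per the sample titles. The ipsilateral hippocampus is the injured side. Each genotype had 8 libraries. The labels say that both sides were collected from 2 replicates of each genotype and time, so the libraries of the sides with the same number were taken to come from the same animal, which the labels do not say outright. The 8 libraries titled NEIL2-KO carried the genotype tag NEIL1-KO in the labels and were grouped by their titles. RNA was extracted with the Qiagen AllPrep kit, its quality was measured on an Agilent Bioanalyzer with an RNA Pico chip, and libraries followed standard Illumina protocols, per the labels' protocols. Whether the libraries or the counting used strand was not stated, so reads of a gene and of an overlapping antisense gene cannot be told apart.

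The deposited table held 1 signal per gene and library, and this signal was a size-factor normalized read count. Per the submitters' processing notes, the tools were Trim Galore, HISAT2, SAMtools, featureCounts and DESeq2, and the genome build was GRCm39 (mm39). Tool versions and settings were not given in the sources used here. Within each library every deposited value was a whole multiple of the value of 1 read, to a tolerance of 1e-06 for 100% of values, so whole reads were recovered from the table. The table had 33084 lines, of which 10770 (32.55%) carried no gene name and 22314 did. For the 24 symbols on several lines, which repeated a symbol 31 times, each line was kept apart. Depth was 17771293 to 29252067 reads per library over the whole table and 16231616 to 26292997 reads on named genes. The intervals given for ratios of reads cover counting error only, since the reads carried no molecular identifiers.

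Genes with a deposited value of at least 10 in at least 2 of the 24 libraries were tested, which left 18364 genes (82.3% of those named). Values were analysed as log2(value + 1) with limma-trend (limma 3.58.1 in R 4.3.3), with a mean for each of the 12 groups and a spread shared by all of them, which gave 12 residual degrees of freedom. A gene was called at a two-sided Benjamini-Hochberg adjusted p under 0.05 over all genes tested in the comparison. There were 15 comparisons. The sides were compared within each genotype and time. Each knockout was compared with wild type on each side, as the mean over both times. The side responses (ipsilateral minus contralateral) were compared between genotypes and between times, and 6 h was compared with 3 h on the contralateral side. Log2 fold changes are given with their standard error (SE) from this fit, and group levels as mean ± SD of the normalized counts. The replicates of a group were different animals, and p-values measure the spread between these animals. Fitted fold changes of genes with few reads on one side depend on the added pseudocount of 1, so pooled reads are given for these.

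Gene lists for stress and injury responses, DNA repair, synapse and metabolism, and markers of cell types and neighbouring tissues were fixed before the data were examined, as were the test, the comparisons, the first set of alternative analyses and the rule for named genes. Of 30 lists, 28 were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each with Benjamini-Hochberg adjustment over the lists. Members past the threshold were counted over all genes tested and with p-values adjusted over the list alone. The list of sex-linked genes served only to describe libraries, and the 13 genes encoded by mitochondrial DNA were absent from the genes tested.

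Genes were named by the following rule. Neil1 and Neil2 were reported in every group. For the sides in wild type, the 10 highest and 10 lowest log2 fold changes among called genes were taken, leaving out names of predicted genes and pseudogenes, genes with a mean value under 50 in the compared groups, and genes whose replicates of the compared groups overlapped. The knockouts were described with the same genes. The other comparisons used the same rule with their own genes. In each list up to 4 members with the smallest adjusted p were named, and members with a textbook role that were not called were given as values only. Some members are not reported here.

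The alternative analyses set in advance were a pseudocount of 5, no filter on low values, TMM scaling and the quasi-likelihood test of edgeR 4.0.16, the Wald test of DESeq2 1.42.0, only the compared groups in the fit, a fit with replicate number or animal as a block, and leaving out each library in turn. A sex term, leaving out animals with high Xist, leaving out an outlying library, a term for choroid plexus markers, and splitting the wild-type libraries between the knockouts were added after the data were seen. Xist, the X-inactivation transcript, was high in the same number on both sides in all 3 genotype and time sets that held both sexes, and could not check the pairing by number in the other 3 sets. The correlation across genes between the deviations of same-numbered libraries of the 2 sides was -0.00576 and -0.00334 in wild type (3 h and 6 h), 0.271 and 0.155 in labelled Neil1-KO and 0.0537 and 0.035 in Neil2-KO, so the pairing stays unchecked in wild type and in Neil2-KO at 3 h. Across genotypes and times the animals shared only a number. Positions came from a RefSeq table of assembly GRCm38.p6, which is not the build of the deposited table, and were used only to say which genes share a chromosome or neighbour each other.

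The tests were run on simulated data with known changes. Of the genes changed by 1.5, 2 and 4 times in simulated libraries, 20.9%, 74.6% and 98.5% were called in the comparison of the sides in wild type at 3 h (67, 67 and 66 changed genes among 18364). The shares were 70.1%, 95.5% and 100% for labelled Neil1-KO against wild type on the contralateral side. They were 28.4%, 74.6% and 97% for the difference of side response between Neil2-KO and wild type, and 59.7%, 85.1% and 100% for the difference between times. False calls made up 3.01%, 2.75%, 3.62% and 4.12% of the calls in these 4 tests. The changed genes were drawn from those with a mean value of at least 50, so the shares do not cover genes with lower values. In the simulation each gene had the same spread in all groups and no library was outlying. The shares need not hold in the real libraries, whose groups differed in spread.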

Results

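Hippocampal RNA was sequenced after neonatal hypoxia-ischemia in mice labelled as lacking Neil1 or Neil2, a pair of DNA glycosylases that remove oxidized bases in base excision repair, and in wild-type (WT) mice. The 24 libraries formed 12 groups of 2 animals each: 3 genotypes, the contralateral and the injured ipsilateral side, and 3 h and 6 h. Each library held between 17771293 and 29252067 reads. The first principal component (40.3% of the variance) separated the sides, with contralateral libraries between -43.94 and -24.68 and ipsilateral ones between 12.39 and 75.76. The highest value belonged to labelled Neil1-KO ipsilateral 6 h replicate 2, which also had the lowest second component (-56.52) and 12.48% of its counts on unnamed genes. The median SD between replicates (log2) was 0.0813 to 0.159 in the contralateral groups and 0.077 to 0.23 in the ipsilateral groups, the highest of these in labelled Neil1-KO at 6 h. Xist, expressed from the inactive X chromosome, was high (7604 to 18160 normalized counts) on both sides in replicate 2 of labelled Neil1-KO at 3 h and at 6 h and in replicate 2 of Neil2-KO at 6 h. All WT libraries had Xist between 4.94 and 20.2, so all WT animals were male by this measure. Ttr, the transthyretin transcript that choroid plexus makes in abundance, ranged from 73.96 to 35650 normalized counts. It exceeded 10000 in 8 libraries (5 contralateral and 3 ipsilateral) and lay under 1000 in 14.

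**Figure D1:**
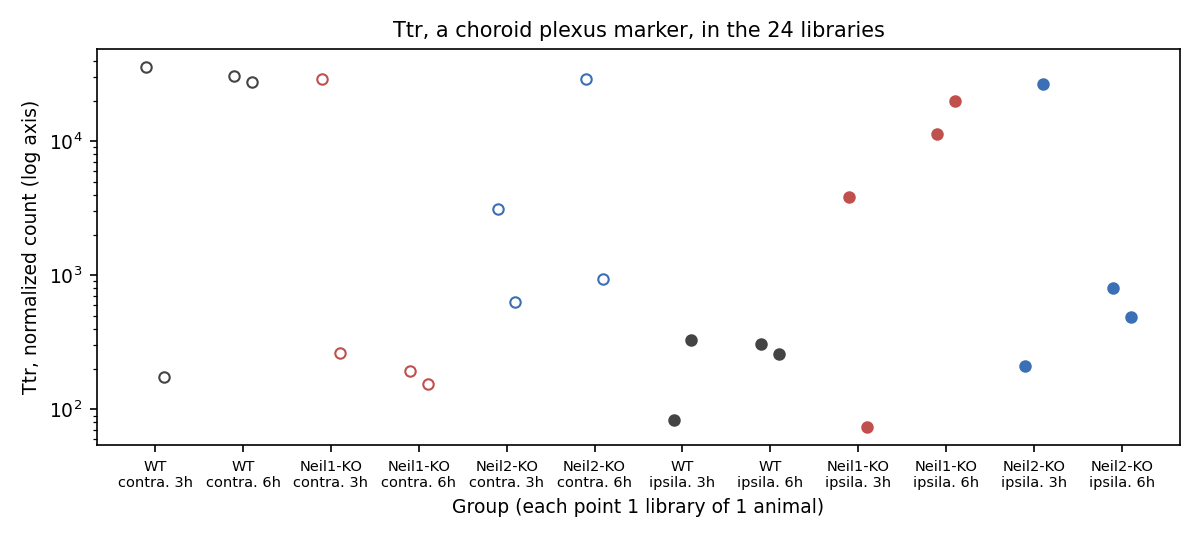
Ttr, a choroid plexus transcript, in each of the 24 libraries (normalized counts, log axis) by genotype, side and time, with 1 point per library. The 8 libraries above 10000 included 3 of the 4 WT contralateral libraries and none of the 4 WT ipsilateral ones, whose highest value was 330.6.

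The targeted genes were examined in every group first, as a check of the labels. Neil2 was nearly lost in the Neil2-KO libraries, at 1.093 ± 1.18 normalized counts (SD, n = 8 libraries) against 20.68 ± 4.66 in WT and 23.28 ± 4.59 in labelled Neil1-KO. The pooled reads were 9 in Neil2-KO and 163 in WT, which is 5.25% of the WT level (exact 95% counting interval 2.36% to 10.2%). Neil1 was not lower in the libraries labelled Neil1-KO. It stood at 125.8 ± 23.3 there, at 97.99 ± 22.2 in WT and at 97.43 ± 27 in Neil2-KO (SD, n = 8 libraries each), with ranges that overlapped between labelled Neil1-KO and WT. The pooled Neil1 reads were 1034 in labelled Neil1-KO and 778 in WT, or 131% of the WT level (exact 95% counting interval 120% to 144%). The Neil1 difference from WT was not called on either side. Its log2 fold change was 0.43 ± 0.16 (SE) contralaterally, and the limma Benjamini-Hochberg adjusted p was 0.565 contralaterally and 0.203 ipsilaterally. Which part of either gene was removed was not given in the sources used here, and reads outside a deleted part would check nothing. The Neil1 counts therefore leave the Neil1-KO label unverified, and every comparison of these libraries concerns the libraries labelled Neil1-KO.

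**Figure D2:**
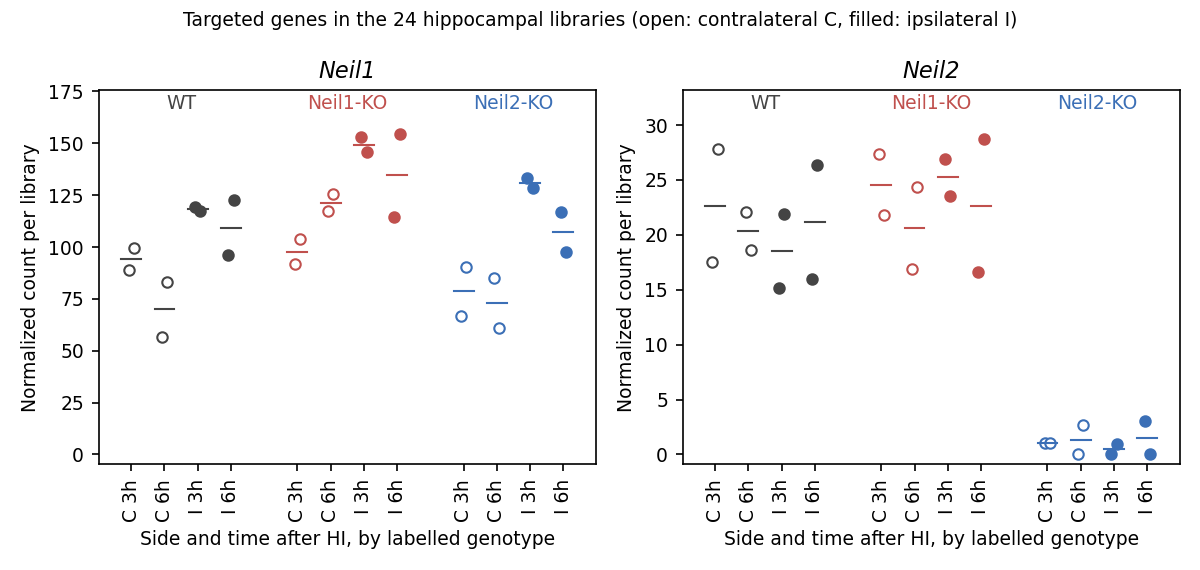
Neil1 and Neil2 in normalized counts per library in WT, labelled Neil1-KO and Neil2-KO. Each point is 1 library, and each line is the mean of the 2 libraries of a genotype, side and time. Neil2 lay between 0 and 3.019 in Neil2-KO and between 15.15 and 27.78 in WT, while Neil1 in labelled Neil1-KO (91.64 to 154.6) overlapped WT (56.75 to 122.6).

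In WT at 3 h, genes for chemokines, heat shock proteins and stress-induced factors rose on the ipsilateral side. The chemokine genes Ccl4 (log2 fold change 6.76 ± 0.73, SE, n = 2 libraries per side), Ccl3 (6.45 ± 0.83), Ccl2 (5.16 ± 0.66) and Ccl7 (3.93 ± 0.62) were among the 10 largest increases. Ccl4 went from 3.32 ± 3.06 normalized counts contralaterally to 407.9 ± 81.3 ipsilaterally (SD, n = 2). Hspa1a and Hspa1b, which encode the inducible chaperone Hsp70, rose by 4.78 ± 0.36 and 4.88 ± 0.37, and Hspa1a reached 11350 ± 1990 from 413.8 ± 90.8. As near-identical copies, this pair may share reads, and the split between them is uncertain. Gdf15, a stress-induced cytokine (5.07 ± 0.71), Atf3, a stress-induced transcription factor (4.55 ± 0.78), Il1a, an inflammatory cytokine (4.38 ± 0.74), and Zfp36, which destabilizes cytokine transcripts (4.11 ± 0.35), completed the 10. The largest decreases included Bdnf, a growth factor for neurons (-1.54 ± 0.36, from 1991 ± 47.8 to 685.1 ± 95.8), the pentraxin gene Nptx2 (-1.49 ± 0.32), and the potassium channel genes Kcna1 (-1.38 ± 0.33) and Kcnk6 (-1.55 ± 0.31). Bmp3 (-1.77 ± 0.24), Lipg (-1.69 ± 0.45), Ccnf (-1.49 ± 0.32), Tbx2 (-1.47 ± 0.31), Kctd16 (-1.47 ± 0.35) and Ankrd33b (-1.40 ± 0.27) fell as well. Limma adjusted p-values (Benjamini-Hochberg) of these 20 genes ran from 1.06e-06 for Hspa1a to 0.0421 for Lipg.

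Among the groups of genes at 3 h in WT, immediate early genes, which respond to stimuli without new protein synthesis, rose for 16 of 25 members, with Klf4 (3.72), Ier2 (3.15 ± 0.28), Ier3 (3.06) and Nr4a1 (2.64) among them. In this group 1 member, the transcription factor Egr3, fell (-1.37), and 8 did not pass the test. The counts were 19 higher and 2 lower adjusted over the list alone (camera adjusted p = 7.91e-20, and adjusted p = 0.0307 with an estimated correlation). Of 22 cytokine, chemokine and NF-kB target genes 15 rose, such as Socs3 (3.48 ± 0.33) and Nfkbiz (2.13), while Ptgs2, the inducible cyclooxygenase, fell (-1.12) and 6 did not pass. This list had 17 higher and 1 lower adjusted over the list alone (camera adjusted p = 7.91e-20, and adjusted p = 0.0177 with an estimated correlation). Of 16 heat shock genes 11 rose, among them Hspb1 (3.49) and Dnajb1 (1.53 ± 0.15), and 5 did not pass. There were 13 adjusted over the list alone (camera adjusted p = 2.1e-15, and adjusted p = 0.0307 with an estimated correlation). Genes of the integrated stress response and unfolded protein response rose for 4 of 16 members, namely Ppp1r15a (1.23), Ddit3 (0.91), Hspa5 (0.81) and Atf4 (0.79). The count was 8 adjusted over the list alone, and the camera call (adjusted p = 3.81e-05) was lost with an adjusted p = 0.288 with an estimated correlation. Glutamate synapse genes fell for 9 of 23 members, with Homer1 (-1.36 ± 0.23), Shank3 (-0.87 ± 0.14), Nlgn1 (-0.73) and Dlgap1 (-0.71), and 14 did not pass. A total of 15 were lower adjusted over the list alone, with a camera adjusted p = 7e-12 and an adjusted p = 0.288 with an estimated correlation. In total 787 of 18364 genes were called by limma at 3 h in WT, 458 higher and 329 lower, of which 267 rose and 34 fell at least 2-fold. The count moved by over 1.5 times without WT contralateral replicate 2 (167 called), ipsilateral replicate 1 (275) or ipsilateral replicate 2 (155). It was higher with only the compared groups in the fit (1946), with DESeq2 (1304), with a term for choroid plexus markers (1273), among animals with low Xist (1585) and without the outlying library (1636). Of the 20 named genes 9 stayed called without each library: Ccl4, Ccl3, Ccl2, Ccl7, Gdf15, Hspa1a, Hspa1b, Zfp36 and, as the only decrease, Bmp3. Bdnf lost the call in each of the 4 fits without a library.

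In WT at 6 h chemokine and stress genes were again higher on the ipsilateral side. Ccl4 went from 0.9619 ± 1.36 to 578.5 ± 124 normalized counts (SD, n = 2 libraries per side); its pooled reads were 2 and 1345, a ratio of 565 (exact 95% counting interval 156 to 4670). Atf3 rose by 6.99 (24.66 ± 3.22 to 3348 ± 1130), Ccl2 by 6.19, Ccl3 by 5.94, Gdf15 by 5.94, Hspa1b by 4.71 and Hspa1a by 4.60. At 3 h Atf3 had stood at 248.6 ± 276 contralaterally and 3655 ± 416 ipsilaterally. Its larger difference at 6 h thus came with a lower contralateral level. Cxcl10, an interferon-induced chemokine (4.91 ± 1.13, SE), Maff, a small Maf transcription factor (4.85 ± 0.32, from 26.58 ± 5.94 to 822.8 ± 347), and Bdkrb2, the bradykinin B2 receptor (4.57 ± 0.45), completed the 10 largest increases. Thsd4 fell by 2.90 (SE 0.36, from 1858 ± 62.9 to 265.4 ± 133), and Nr3c2, the mineralocorticoid receptor, had a log2 fold change of -2.36 ± 0.48. Car12 (-2.87 ± 0.47), Lct (-2.68 ± 0.58), Lipg (-2.51), Sult1a1 (-2.46 ± 0.38), the protocadherin gene Pcdh20 (-2.34 ± 0.37) and the cytokine gene Il16 (-2.32 ± 0.44) fell too. The lowest values under the naming rule were those of Folr1 (-4.17 ± 1.26, from 185 ± 67.1 to 8.976 ± 0.106) and Cldn2 (-3.88 ± 1.05), both expressed in choroid plexus. They moved with Ttr, which was above 10000 in both WT contralateral libraries at 6 h and at most 330.6 in the WT ipsilateral ones (log2 fold change -6.69 ± 2.503, not called). Limma adjusted p-values (Benjamini-Hochberg) of these genes ran from 3.09e-07 for Maff to 0.0262 for Folr1.

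Of 22 cytokine and NF-kB genes 20 rose at 6 h in WT, Ptgs2 again fell (-1.10), and 1 did not pass. The counts stayed at 20 and 1 adjusted over the list alone (camera adjusted p = 1.01e-15, and adjusted p = 0.0434 with an estimated correlation). Immediate early genes rose for 19 of 25, among them Ier3 (3.89), Ier2 (3.28) and Junb (2.30), and Egr3 fell (-1.07). These counts were also 19 and 1 adjusted over the list alone, and the camera adjusted p = 1.01e-15 stood beside an adjusted p = 0.0667 with an estimated correlation. Genes of the integrated stress and unfolded protein response rose for 13 of 16, including Ppp1r15a (2.14 ± 0.19), Ddit3 (1.64), Hspa5 (1.62) and Creld2 (1.11). That was 13 adjusted over the list alone (camera adjusted p = 9.13e-12, and adjusted p = 0.0514 with an estimated correlation). Heat shock genes rose for 12 of 16 (13 adjusted over the list alone; camera adjusted p = 2.46e-09, and adjusted p = 0.0894 with an estimated correlation). Glutamate synapse genes fell for 15 of 23, among them the NMDA receptor subunit genes Grin2b (-2.22 ± 0.32) and Grin2a (-2.00 ± 0.31), and 8 did not pass. With p-values adjusted over the list alone 18 were lower and 1 higher (camera adjusted p = 4.12e-10, and adjusted p = 0.265 with an estimated correlation). GABA signalling genes fell for 6 of 17, with Gabra2 (-1.38) and Gabra5 (-1.11) among them (8 adjusted over the list alone; camera adjusted p = 0.00107, and adjusted p = 0.269 with an estimated correlation). Markers of hippocampal subfields fell for 7 of 12, including Prox1 of the dentate gyrus (-2.15) and Fibcd1 of CA1 (-2.09 ± 0.42). Their count was also 7 adjusted over the list alone (camera adjusted p = 0.000399, and adjusted p = 0.139 with an estimated correlation). Beside them, the thalamus marker Tcf7l2, singled out after the data were seen, was 582.1 and 939.6 normalized counts in the WT ipsilateral libraries at 6 h and 177.9 and 152.9 contralaterally. The result of the list of 10 thalamus markers is not reported here. Striatum markers were higher for 5 of 10, among them Drd1 (1.39) and Drd2 (1.15), and lower for 2, with the same counts adjusted over the list alone (camera adjusted p = 0.145). Reactive astrocyte genes rose for 9 of 16, such as Cd14 (3.97), Emp1 (3.61) and Cd44 (2.20). It was also 9 adjusted over the list alone (camera adjusted p = 1.46e-06, and adjusted p = 0.269 with an estimated correlation). Choroid plexus markers fell for 3 of 10, Kcnj13 (-4.57), Folr1 and Kl (-1.32). Of these markers 7 were lower adjusted over the list alone (camera adjusted p = 0.0015, and adjusted p = 0.554 with an estimated correlation). Limma called 3785 genes, 1901 higher and 1884 lower, of which 812 rose and 414 fell at least 2-fold. The count moved by over 1.5 times without WT contralateral replicate 1 (2214), contralateral replicate 2 (1574) or ipsilateral replicate 2 (1967), and was 2509 with only the compared groups in the fit. Cxcl10, Folr1, Cldn2 and Lct were the named genes not called in every such fit.

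The genes named for WT were also examined in the knockouts. Ccl4 rose by 6.61 in labelled Neil1-KO and by 6.97 in Neil2-KO at 3 h, Ccl2 by 4.82 and 6.67, Hspa1a by 5.73 and 4.78, Atf3 by 7.41 and 5.97, and Zfp36 by 4.40 and 4.59 (log2, n = 2 libraries per side). At 6 h Maff rose by 5.49 and 4.90, Atf3 by 6.91 and 6.33, and Bdkrb2 by 3.77 and 3.04. Where the contralateral side held few reads, as for Ccl4 in labelled Neil1-KO at 6 h (2 against 1489 reads, a ratio of 719 with an exact 95% counting interval of 199 to 5950), fitted values depend on the pseudocount. All 10 genes named for their increase in WT were called higher in each knockout at each time. Of the 10 named for their decrease, 6 were called lower in labelled Neil1-KO at 3 h (not Kcnk6, Ccnf, Nptx2 and Tbx2) and 8 in Neil2-KO (not Lipg and Bdnf). At 6 h 6 were called in labelled Neil1-KO (not Folr1, Cldn2, Car12 and Sult1a1) and 6 in Neil2-KO (not Folr1, Cldn2, Nr3c2 and Il16). Folr1 stood at a log2 fold change of 3.04 in labelled Neil1-KO at 6 h (limma adjusted p = 0.0653), where Ttr was 11310 and 19800 normalized counts in the ipsilateral libraries.

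Cytokine and NF-kB genes rose for 20 of 22 in labelled Neil1-KO and 19 of 22 in Neil2-KO at 3 h, and for 20 of 22 in each at 6 h. For labelled Neil1-KO at 3 h, Neil2-KO at 3 h, Neil2-KO at 6 h and labelled Neil1-KO at 6 h these counts were 20, 21, 20 and 21 adjusted over the list alone. The camera calls held with an estimated correlation (adjusted p = 0.0322, 0.0106, 0.0249 and 0.0466). Immediate early genes rose at 3 h for 20 of 25 in labelled Neil1-KO (20 adjusted over the list alone) and 17 of 25 in Neil2-KO (18), with adjusted p = 0.0388 and 0.0233 with an estimated correlation. Glutamate synapse genes fell for 17 and 13 of 23 at 3 h and for 21 and 19 of 23 at 6 h in labelled Neil1-KO and Neil2-KO, with Grin2b at -3.08 in labelled Neil1-KO at 6 h. With p-values adjusted over the list alone, the counts were 21 and 16, then 21 and 20. The camera adjusted p with an estimated correlation was 0.237, 0.345, 0.126 and 0.187. All 12 neuron markers, such as Map2 (-1.06), Syt1 (-0.97) and Nefl (-0.95), fell in labelled Neil1-KO at 6 h (12 adjusted over the list alone; camera adjusted p = 7.65e-07, and adjusted p = 0.202 with an estimated correlation). In Neil2-KO at 6 h 8 of these 12 fell (10 adjusted over the list alone; camera adjusted p = 1.24e-05, and adjusted p = 0.333 with an estimated correlation). Reactive astrocyte genes rose for 15 of 16 in labelled Neil1-KO at 6 h, with Cd14 at 5.10 and Vim at 2.34. In Neil2-KO 10 of 16 rose at 6 h (16 and 13 adjusted over the list alone; adjusted p = 0.126 and 0.217 with an estimated correlation).

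Limma called 3130 genes between the sides in labelled Neil1-KO at 3 h (1322 higher, 1808 lower) and 7156 at 6 h (3229 higher, 3927 lower). In Neil2-KO it called 1696 at 3 h (787 higher, 909 lower) and 4552 at 6 h (2234 higher, 2318 lower). Of the 787 genes called in WT at 3 h, 673 were called in the same direction in labelled Neil1-KO and 654 in Neil2-KO, against 65.36 and 35.91 for independent lists, and 0 in the opposite direction. Of the 3785 called in WT at 6 h, 2618 and 2365 were shared in direction (737.1 and 469.1 for independent lists) and 8 and 5 were opposite. These comparisons share no libraries. Across genes, which are not independent replicates, the fold changes of WT correlated with those of labelled Neil1-KO at r = 0.693 (3 h) and 0.612 (6 h) and with those of Neil2-KO at 0.708 and 0.71. The counts moved by over 1.5 times without a library in each knockout set. At 3 h in labelled Neil1-KO 1635 genes were called without contralateral replicate 1, 1231 without contralateral replicate 2 and 1270 without ipsilateral replicate 1. At 6 h the count was 4629 without contralateral replicate 1 and 3991 without ipsilateral replicate 2. In Neil2-KO at 3 h the count was 511 without contralateral replicate 1, 765 without contralateral replicate 2, 963 without ipsilateral replicate 1 and 289 without ipsilateral replicate 2. At 6 h it was 2525 without contralateral replicate 2 and 2074 without ipsilateral replicate 1. With only the compared groups in the fit the counts at 3 h were 1946 in WT, 1852 in labelled Neil1-KO and 2790 in Neil2-KO, and at 6 h 2509, 2685 and 4182, so the order of the genotypes depended on the fit at both times. Among animals with low Xist 2996 genes were called in labelled Neil1-KO at 6 h, and without the outlying library 2595 in Neil2-KO at 3 h.

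**Figure D3:**
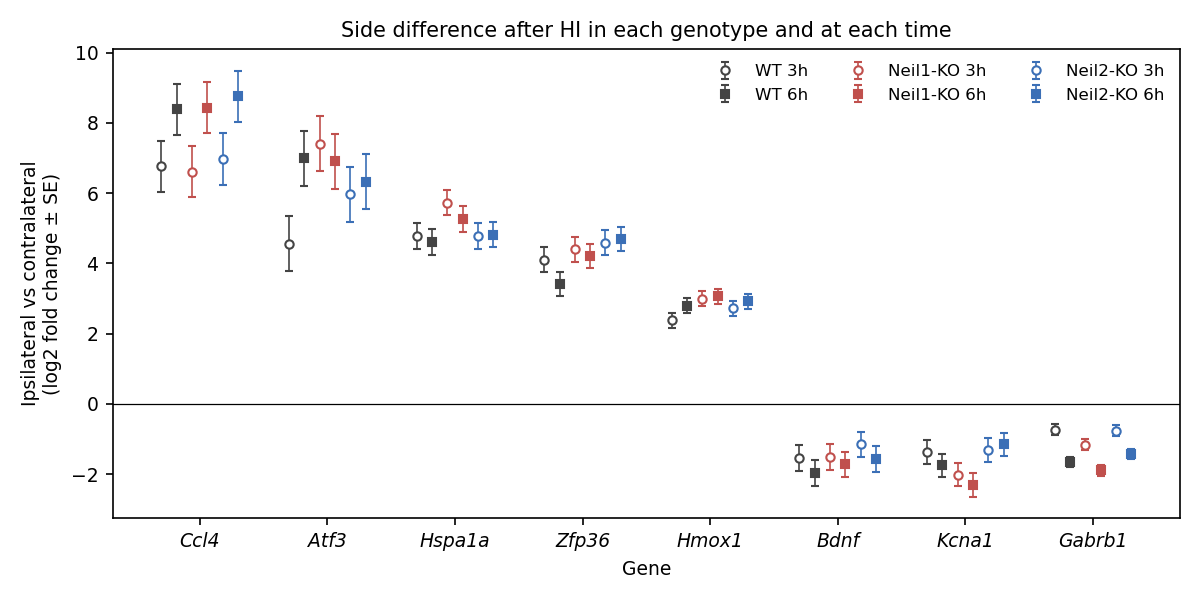
Log2 fold change (ipsilateral minus contralateral, with SE, n = 2 libraries per side) in WT, labelled Neil1-KO and Neil2-KO at 3 h and 6 h. The genes shown are Ccl4, Atf3, Hspa1a, Zfp36, Hmox1, Bdnf, Kcna1 and Gabrb1. Ccl4 lay between 6.61 and 8.76 in all 6 sets.

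Whether the genotypes differed in the response of the injured side relative to the other was tested as the difference of side responses, averaged over both times. No group was free of hypoxia-ischemia, so changes common to both sides do not show in this difference. Limma called 0 genes for labelled Neil1-KO against WT, 0 for Neil2-KO against WT and 0 between the knockouts. There were 2652, 976 and 1844 genes at an unadjusted p under 0.05, with smallest Benjamini-Hochberg adjusted p-values of 0.303, 0.275 and 0.467. By comparison, edgeR called 0, 0 and 0, and DESeq2 called 5, 1 and 3. The genes called by DESeq2, named here after their values were seen, were Trip10 (1.29), Layn (1.08), Metap1d (0.853), Scn2b (-0.875) and Ccdc177 (-1.02) for labelled Neil1-KO. They were Metap1d (0.992) for Neil2-KO and Htr2c (1.01), Spsb1 (-0.725) and Tmem119 (-2.23) between the knockouts. Glutamate synapse genes had a median difference of -0.46 (log2) in labelled Neil1-KO against WT, and 0 of 23 members were called by limma. As few as 0 passed adjusted over the list alone either (camera adjusted p = 2.54e-07, and adjusted p = 0.327 with an estimated correlation). Neuron markers had a median of -0.35 with 0 of 12 called and 4 lower adjusted over the list alone (camera adjusted p = 1.85e-05, and adjusted p = 0.327 with an estimated correlation). Choroid plexus markers had a median of 3.01, with 0 of 10 called and 2 higher adjusted over the list alone (camera adjusted p = 1.13e-05, and adjusted p = 0.327 with an estimated correlation). For Neil2-KO against WT the cytokine and NF-kB genes had a median of 0.70 with 0 of 22 called, also 0 adjusted over the list alone (camera adjusted p = 2.3e-05, and adjusted p = 0.8 with an estimated correlation). The median SE of these differences was 0.1883, and the counts of 0 moved when some single libraries were left out. Each such fit left 1 library in a group. Without labelled Neil1-KO ipsilateral 6 h replicate 1 that library was the outlying one, so the counts of that fit may reflect it alone. Without labelled Neil1-KO ipsilateral 6 h replicate 1, 2101 genes were called against WT and 801 between the knockouts. Without WT ipsilateral 6 h replicate 1 the counts were 174 for labelled Neil1-KO and 50 for Neil2-KO. Without labelled Neil1-KO ipsilateral 3 h replicate 2 the count between the knockouts was 1 (Htr2c, 1.26).

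On the contralateral side, limma called 19 genes between labelled Neil1-KO and WT, while 117 were called with only the compared groups in the fit, 84 by DESeq2, 31 without the outlying library and 10 among animals with low Xist. Plac9a (log2 fold change 1.64 ± 0.18, SE, n = 4 libraries per genotype), Duxbl1 (1.44 ± 0.19), Tmem254a (1.201 ± 0.10), Entpd4b (0.99 ± 0.10) and Entpd4 (0.98 ± 0.10) were higher, and Neo1, a netrin and RGM receptor, was higher by 0.52 ± 0.08. Plac9a stood at 143.4 ± 6.44 and 185.5 ± 6.62 normalized counts in WT at 3 h and 6 h and at 558.8 ± 90.7 and 467.4 ± 8.24 in labelled Neil1-KO (SD, n = 2). Plac9a, Tmem254a, Duxbl1 and the Entpd4 pair have near-identical copies in the mouse genome, so their counts are uncertain where counting splits reads. Htr3a, the ionotropic serotonin receptor of interneurons, was lower (-1.83 ± 0.28), at 37.77 ± 6.81 and 43.83 ± 6.79 against 153.6 ± 6.05 and 140.6 ± 16 in WT. Layn (-1.53 ± 0.14), Pts, an enzyme of tetrahydrobiopterin synthesis (-1.02 ± 0.12), the ubiquitin ligase gene Cbl (-0.92 ± 0.11), Nxpe4 (-0.91 ± 0.10), Rasd1 (-0.84 ± 0.15), Nlrx1 (-0.84 ± 0.13), the imprinted gene Ndn (-0.77 ± 0.08) and Sdhd, a subunit of succinate dehydrogenase (-0.41 ± 0.06), were lower as well. Limma adjusted p-values (Benjamini-Hochberg) included 8.49e-06 for Tmem254a, 2.23e-05 for Layn and 0.00432 for Htr3a. Of the 19 genes called (8 higher, 11 lower), 9 lie on the chromosome of Neil1 in assembly GRCm38.p6, among them Htr3a, Layn, Pts, Cbl, Nxpe4, Nlrx1, Sdhd and Neo1.

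Of the gene lists, glucocorticoid-responsive genes were lower in labelled Neil1-KO contralaterally under both forms of camera (adjusted p = 2.63e-11, and adjusted p = 0.0233 with an estimated correlation). Of its 14 members 1 was called, Klf9 (-0.42 ± 0.07), and 6 were lower adjusted over the list alone; Sgk1 stood at -0.53, Errfi1 at -0.49 and Fkbp5 at -0.36. Oligodendrocyte markers had 0 of 11 members called and 8 lower adjusted over the list alone (camera adjusted p = 1.12e-10, and adjusted p = 0.134 with an estimated correlation). The myelin gene Mbp ranged from 2198 to 2753 normalized counts in the 4 labelled Neil1-KO contralateral libraries and from 3335 to 8946 in the 4 WT ones. In the same libraries Ttr was above 10000 in 1 labelled Neil1-KO library and in 3 WT ones. Immediate early genes had 0 of 25 called and 5 lower adjusted over the list alone (camera adjusted p = 2.63e-11, and adjusted p = 0.134 with an estimated correlation). Without WT contralateral 3 h replicate 2 the count of called genes was 33, and Neo1, Rasd1 and Nlrx1 were the named genes not called in every fit without a library. Among animals with low Xist these 3 and Duxbl1, Htr3a and Sdhd were not called, so 9 of the 15 named genes were called in every alternative run.

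On the ipsilateral side, Ndn was lower and Plac9a and Tmem254a were higher in labelled Neil1-KO than in WT, and of the 20 named genes only these 3 were called in every alternative run. Scn2b, a sodium channel subunit (log2 fold change -1.36 ± 0.13, SE, n = 4 libraries per genotype), went from 1274 ± 192 and 757.5 ± 49.2 normalized counts in WT at 3 h and 6 h to 498 ± 58 and 298.8 ± 92.6. Htr3a (-1.99 ± 0.28), the glycine receptor gene Glra3 (-1.60 ± 0.29), Irs4 (-1.32), Dgkk (-1.30), the neurofilament gene Nefh (-1.22 ± 0.26), Ndn (-1.06 ± 0.08), the synaptic vesicle gene Vamp1 (-1.05 ± 0.19), the somatostatin receptor gene Sstr3 (-1.02) and Extl1 (-1.01) were lower too. Plac9a (2.35 ± 0.18), Duxbl1 (1.71 ± 0.19) and Tmem254a (1.29 ± 0.10) were higher as on the other side. Also higher were Ak7 (1.69 ± 0.45), Mns1 (1.23 ± 0.21), Ccdc114 (0.93 ± 0.24) and Cfap46 (0.89 ± 0.23), the collagen genes Col2a1 (1.19 ± 0.22) and Col1a1 (1.07 ± 0.33), and Myb (0.86 ± 0.25). Limma adjusted p-values (Benjamini-Hochberg) ran from 8.85e-07 for Plac9a to 0.0497 for Col1a1. Without at least 1 library 10 of the 20 lost the call, namely Ak7, Ccdc114, Cfap46, Col2a1, Col1a1, Myb, Irs4, Dgkk, Nefh and Sstr3.

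Glutamate synapse genes were lower for 13 of 23 in this comparison, including Slc17a7, the vesicular glutamate transporter (-0.78 ± 0.16). Lower members numbered 19 adjusted over the list alone (camera adjusted p = 3.3e-10, and adjusted p = 0.392 with an estimated correlation). Neuron markers were lower for 7 of 12, such as Syt1 (-0.59 ± 0.10) and Snap25 (-0.54). Here 9 were lower adjusted over the list alone (camera adjusted p = 5.93e-06, and adjusted p = 0.392 with an estimated correlation). GABA signalling genes were lower for 7 of 17, among them Gad2 (-0.60). In this list 11 were lower adjusted over the list alone (camera adjusted p = 0.000147, and adjusted p = 0.392 with an estimated correlation). Cell cycle genes were higher for 7 of 18, with Aurkb (0.77 ± 0.16), Kif11 (0.71), Top2a (0.64) and Cenpe (0.60). Higher members numbered 15 adjusted over the list alone (camera adjusted p = 3.3e-10, and adjusted p = 0.392 with an estimated correlation). Oligodendrocyte markers were lower for 4 of 11, among them Mobp (-2.55 ± 0.58), Mag (-1.75) and Mbp (-1.24 ± 0.31). That number was 5 adjusted over the list alone (camera adjusted p = 0.00121, and adjusted p = 0.452 with an estimated correlation). Beside these groups, Ttr ranged from 73.96 to 19800 normalized counts in the 4 labelled Neil1-KO ipsilateral libraries and from 83.34 to 330.6 in WT. Col1a1 ranged from 1501 to 3562 and from 994.4 to 1413 in the same libraries. Hba-a1, a hemoglobin gene singled out after the data were seen, ranged from 3429 to 14000 and from 2351 to 4533, with its highest value in the outlying library. Limma called 1710 genes, 351 higher and 1359 lower; edgeR called 1659 (535 higher, 1124 lower) and DESeq2 2426 (791 higher, 1635 lower). The count rested on single libraries: without WT 3 h replicate 1 it was 95, without WT 3 h replicate 2 733, without WT 6 h replicate 1 2808 and without WT 6 h replicate 2 313. Without labelled Neil1-KO 3 h replicate 1 it was 170, without 3 h replicate 2 2929, without 6 h replicate 1 5246 and without 6 h replicate 2, the outlying library, 345. With only the compared groups in the fit 4 genes were called, Ndn, Tmem254a, Plac9a and Gm16867, the last of these named after its values were seen. With a term for choroid plexus markers 225 were called, with a sex term 705 and among animals with low Xist 710.

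Between Neil2-KO and WT, limma called 15 genes contralaterally and 20 ipsilaterally, and DESeq2 37 and 38. On the contralateral side Plac9a (log2 fold change 2.16 ± 0.18, SE, n = 4 libraries per genotype) and Tmem254a (1.43 ± 0.10) were higher, at 759.6 ± 36.6 and 3354 ± 254 normalized counts at 3 h against 143.4 ± 6.44 and 1292 ± 13.3 in WT (SD, n = 2). Neil2 itself was lower (-3.48 ± 0.45, a fitted value that depends on the pseudocount), as were Tmem260 (-0.998 ± 0.14), Gfra2, a receptor for neurturin (-0.79 ± 0.13), and Esd, the esterase D gene (-0.73 ± 0.10). Ipsilaterally Plac9a (2.39 ± 0.18), Kirrel2 (1.42 ± 0.18), Duxbl1 (1.41 ± 0.19) and Tmem254a (1.36 ± 0.10) were higher. Neil2 (-3.61 ± 0.45), Ppp1r3e (-0.99 ± 0.18), Gfra2 (-0.90 ± 0.13), Tmem260 (-0.89 ± 0.14), Esd (-0.88 ± 0.10) and Pnma2 (-0.79 ± 0.13) were lower. Limma adjusted p-values (Benjamini-Hochberg) were 5.24e-07 for Tmem254a and 0.0221 for Gfra2 contralaterally, and 0.000591 for Esd and 0.0261 for Ppp1r3e ipsilaterally. Of the gene lists, base excision repair had 1 of 24 members called on each side, Neil2 itself, also 1 adjusted over the list alone. The limma calls were 6 higher and 9 lower contralaterally and 8 higher and 12 lower ipsilaterally. The contralateral count was 9 with a sex term, 9 with a term for choroid plexus markers and 4 among animals with low Xist, and the ipsilateral count was 9 with only the compared groups in the fit. Contralaterally the count was 5 without WT 3 h replicate 1 (Plac9a, Tmem254a, Neil2, and, named after their values were seen, Duxbl1 and Adamdec1). It was 9 without WT 3 h replicate 2 and 3 without WT 6 h replicate 2 (Plac9a, Tmem254a and Neil2). It was 127 without Neil2-KO 6 h replicate 1, 4 without 3 h replicate 2 (Plac9a, Tmem254a, Neil2 and Tmem260) and 7 without 6 h replicate 2. Ipsilaterally it was 364 without WT 6 h replicate 1, 10 without WT 6 h replicate 2, and 11 without any of WT 3 h replicate 1, WT 3 h replicate 2, Neil2-KO 6 h replicate 1 and Neil2-KO 3 h replicate 2. With only the compared groups in the fit Neil2, Gfra2, Tmem260 and Pnma2 were not called ipsilaterally. Of the 8 fits without a library, Ppp1r3e was not called in 6, Pnma2 in 5 and Tmem260 in 3, and Ppp1r3e was not called with a sex term nor Tmem260 among animals with low Xist. Contralaterally Gfra2 was not called in 6 of 8 such fits, Esd in 3 and Tmem260 in 2, and Gfra2 and Tmem260 were not called among animals with low Xist, nor Gfra2 with a term for choroid plexus markers.

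Both knockouts were compared with the same WT libraries, so their calls share chance values. Contralaterally 3 genes, Plac9a, Tmem254a and Duxbl1, were called higher in both and 0 were called lower in both by limma. Independent lists would share 0.00261 and 0.00539 genes. Simulated unchanged groups set against the same WT libraries shared 0. Groups without any change give hardly any calls, so this 0 is no yardstick for the shared genes. With the WT libraries split between the knockouts by replicate number, 8 and 9 genes were called in both under either assignment, and 2 of the 3 genes were among them each time. Ipsilaterally Plac9a, Tmem254a and Duxbl1 were higher and Gfra2 and Pnma2 lower in both (0.153 and 0.888 for independent lists, and 0 simulated, again no yardstick). After the split 8 and 8 were called in both, with 3 of the 5 among them. Across genes, which are not independent replicates, the fold changes of the knockouts correlated at 0.333 contralaterally (0.501 simulated) and 0.537 ipsilaterally (0.502 simulated). After the split the correlations were -0.0387 and 0.0669 contralaterally, and 0.192 and 0.258 ipsilaterally. The covariance was 0.0235 against 0.0247 simulated contralaterally and 0.0498 against 0.0249 ipsilaterally.

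The side response differed between 3 h and 6 h, as the mean over the 3 genotypes. Such a difference can come from a change on either side. Irgm1, an interferon-induced GTPase (difference of log2 fold changes 1.38 ± 0.20, SE, n = 6 libraries per side and time), Pdzrn3, a ubiquitin ligase (1.31 ± 0.14), Sox18, an endothelial transcription factor (1.33 ± 0.24), and the chemokine genes Cxcl1 (2.09 ± 0.47) and Ccl9 (1.92 ± 0.41) were higher at 6 h relative to 3 h. In WT, Irgm1 went from 137.2 to 317.3 normalized counts ipsilaterally and from 137.1 to 107.7 contralaterally (means, n = 2). Gabrb1, a GABA receptor subunit (-0.78 ± 0.12), Mphosph9 (-0.85 ± 0.13), Nlgn1, a synaptic adhesion gene (-0.66 ± 0.13), and the immediate early gene Btg2 (-1.40 ± 0.31) were lower. Gabrb1 fell from contralateral to ipsilateral by 0.73 in WT, 1.16 in labelled Neil1-KO and 0.76 in Neil2-KO at 3 h, and by 1.65, 1.90 and 1.43 at 6 h. Reactive astrocyte genes were higher for 4 of 16, Cd44 (1.60 ± 0.28), Timp1 (1.62), Emp1 (1.46) and Osmr (1.24 ± 0.29). They numbered 7 adjusted over the list alone (camera adjusted p = 1.49e-09, and adjusted p = 0.182 with an estimated correlation). Genes of the integrated stress and unfolded protein response were higher for 3 of 16, Creld2 (0.76 ± 0.12), Atf5 (0.55) and Xbp1 (0.46). As many as 11 were higher adjusted over the list alone (camera adjusted p = 1.49e-09, and adjusted p = 0.182 with an estimated correlation). Interferon response genes were higher for 2 of 18, Ifit1 (1.99 ± 0.40) and Gbp2 (1.76), and for 5 adjusted over the list alone (camera adjusted p = 3.23e-05, and adjusted p = 0.182 with an estimated correlation). Cytokine and NF-kB genes were higher for 3 of 22, among them Icam1 (1.39) and Ccl12 (1.60), and for 5 adjusted over the list alone (camera adjusted p = 9.76e-06, and adjusted p = 0.182 with an estimated correlation). Glutamate synapse genes were lower for 2 of 23, Nlgn1 and Gria3 (-0.46), and for 12 adjusted over the list alone (camera adjusted p = 1.99e-07, and adjusted p = 0.33 with an estimated correlation). Limma called 348 genes, 263 higher and 85 lower, with Benjamini-Hochberg adjusted p-values of 0.000709 for Pdzrn3 and 0.00449 for Irgm1. Both genes were called in every alternative run, and 15 of the 20 named genes lost the call without at least 1 library. DESeq2 called 798, and limma called 561 with a term for choroid plexus markers and 24 among animals with low Xist. The count was 125 without WT contralateral 3 h replicate 1, 204 without WT contralateral 6 h replicate 1, 113 without WT contralateral 6 h replicate 2, 63 without WT ipsilateral 3 h replicate 1, 164 without WT ipsilateral 3 h replicate 2 and 544 without WT ipsilateral 6 h replicate 1. Without a labelled Neil1-KO library it was 72 (contralateral 3 h replicate 1), 122 (contralateral 6 h replicate 1), 108 (contralateral 6 h replicate 2), 1405 (ipsilateral 6 h replicate 1) and 535 (ipsilateral 6 h replicate 2). Without a Neil2-KO library it was 157 (contralateral 3 h replicate 2), 156 (contralateral 6 h replicate 2), 82 (ipsilateral 3 h replicate 1), 563 (ipsilateral 3 h replicate 2), 109 (ipsilateral 6 h replicate 1) and 180 (ipsilateral 6 h replicate 2).

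On the contralateral side, immediate early and glucocorticoid-responsive genes were lower at 6 h than at 3 h, as the mean over the 3 genotypes. Of 25 immediate early genes 6 were lower, among them Junb (log2 fold change -0.98 ± 0.11, SE, n = 6 libraries per time), Fosb (-2.09 ± 0.31), Fos (-2.07 ± 0.32) and Maff (-1.14). As many as 19 were lower adjusted over the list alone (camera adjusted p = 8.75e-21, and adjusted p = 0.038 with an estimated correlation). Fos went from 3267 ± 2205 to 282.2 ± 148 normalized counts in WT, from 688.8 to 159.4 in labelled Neil1-KO and from 1155 to 597.8 in Neil2-KO (means, n = 2). Of 14 glucocorticoid-responsive genes 5 were lower, including Per1, a clock gene (-0.60), Zbtb16 (-0.59 ± 0.10), Klf9 (-0.37 ± 0.06) and Tsc22d3 (-0.36). There 8 were lower adjusted over the list alone (camera adjusted p = 1.57e-09, and adjusted p = 0.038 with an estimated correlation). Csrnp1 had the lowest log2 fold change under the naming rule (-1.25 ± 0.12, limma Benjamini-Hochberg adjusted p = 0.000102), and went from 395.6 ± 127 to 101.1 ± 21.6 in WT. Rfx4 (-0.71 ± 0.13) and Pgs1 (-0.30 ± 0.06) were lower too, and Flrt2 (0.47 ± 0.08), Tmtc3 (0.43), Rfx7 (0.37) and Cilk1 (0.36) were higher at 6 h. Limma called 61 genes, 21 higher and 40 lower. It called 228 with only the compared groups in the fit, 34 with a sex term, 94 with a term for choroid plexus markers, 9 among animals with low Xist and 147 without the outlying library, and DESeq2 called 268. The count was 16 without WT 3 h replicate 1, 34 without WT 6 h replicate 1, 4 without WT 6 h replicate 2 (Csrnp1 and, named after their values were seen, Trib1, Spsb1 and Junb). It was 6 without labelled Neil1-KO 3 h replicate 1, 17 without labelled Neil1-KO 6 h replicate 1 and 11 without labelled Neil1-KO 6 h replicate 2. It was 18 without Neil2-KO 3 h replicate 1, 29 without Neil2-KO 3 h replicate 2 and 34 without Neil2-KO 6 h replicate 2, and of the 8 named genes Csrnp1 alone was called in each of these fits.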

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

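The tests of an outlying library, of spread, of sex, of neighbouring DNA, of a colony difference and of the pairing of the sides were chosen only after the results were seen; the split of the shared wild-type libraries and the other splits of the samples were fixed before their results were seen.

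The side response differed between the times in 348 genes by limma's test of the difference itself, as the mean of 3 genotypes. The largest positive differences of log2 fold change (6 h minus 3 h) under the naming rule were those of Cxcl1 (2.09), Ccl9 (1.92), Map3k19 (1.41), Irgm1 (1.38), Sox18 (1.33), Pdzrn3 (1.31), Rflna (1.26), Osmr (1.24), Efna1 (1.22) and Parp14 (1.22). The largest negative ones were those of Btg2 (-1.40), Mphosph9 (-0.85), Epha7 (-0.82), Htr1a (-0.82), Gabrb1 (-0.78), Dcaf12l2 (-0.72), Ipp (-0.66), Nlgn1 (-0.66), Ank3 (-0.63) and Kcnd2 (-0.63). Reads on genes without a name, which the comparisons of named genes left out, took a larger share of the normalized counts on the ipsilateral side: 10.3% ± 0.871 against 8.88% ± 0.642 contralaterally (SD, n = 12 libraries per side). The difference was 1.416 percentage points, in that direction in 11 of 12 pairs of libraries with the same number (two-sided exact sign-flip permutation p = 0.00146). This test takes such pairs as 1 animal; over all 64 ways to pair the sides within genotype and time, p lay between 0.000977 and 0.00146.

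More genes were called for labelled Neil1-KO against wild type on the ipsilateral side (1710) than on the contralateral side (19), and the difference of side responses itself gave 0 calls by limma (2652 genes at an unadjusted p under 0.05; edgeR 0, DESeq2 5). A sex effect shared by both sides could not by itself make the sides differ, so testing it cannot decide the cause of this pattern. With a sex term the fold changes of the 1710 genes kept a median of 0.978 times their size, and the count fell to 705. A shared sex term thus did not account for the size of these fold changes. This term was common to both sides and could not absorb a sex effect on the ipsilateral side alone, which stays open. All wild-type animals were male by Xist. A single outlying library stays open, since without labelled Neil1-KO ipsilateral 6 h replicate 2 these fold changes kept a median of 0.757 times their size, between the bounds set for and against it, and the count fell to 345. A larger spread on this side than the shared estimate also stays open, since the median SE with the compared groups alone was 1.16 times the shared one (0.155 against 0.133; 1.34 times over the called genes) with fewer degrees of freedom (8.37 against 17.7), and 4 genes were called against 117 contralaterally in that setting, so the order of the sides turned. Choroid plexus content of the samples stays open as well, with no bounds set for or against it. Ttr ranged from 73.96 to 19800 normalized counts in the labelled Neil1-KO ipsilateral libraries and from 83.34 to 330.6 in the wild-type ones. The count also fell with a term for choroid plexus markers, as given above. A biological difference between the genotypes stays open too and may add to these, but Neil1 itself was not lower in the libraries that carry the label.

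Genes called against wild type lay on the chromosome of the targeted gene more often on both sides than other tested genes did, with chromosomes taken from assembly GRCm38.p6. For labelled Neil1-KO on the contralateral side the share was 47.4% (9 of 19 genes, against 5.35% of the others; one-sided exact Fisher p = 2.12e-07), and all 9 lay within 200 tested genes of Neil1, while on the ipsilateral side it was 6.56% (112 of 1708, against 5.28%; p = 0.0168). For Neil2-KO it was 85.7% (12 of 14 besides Neil2, against 3.93%; p = 1.26e-15 by the same exact test), with 5 of them within 200 tested genes of Neil2, and ipsilaterally 84.2% (16 of 19, against 3.91%; p = 3.04e-20), and without the genes also called in labelled Neil1-KO, which flanking DNA of Neil2 does not account for there, 81.8% (9 of 11; p = 1.21e-11) and 78.6% (11 of 14; p = 1.15e-13). This is consistent with flanking DNA of another strain carried along with a targeted allele, which may alter neighbouring genes or how their reads align, and it could have come out the other way. Several called genes on the chromosome of Neil2 were predicted genes lying near each other, beyond 200 tested genes from Neil2. Gm17046 and Gm17121, named after their values were seen, were among them on both sides. The Fisher test counts neighbours as independent, so its p-values overstate the evidence. An effect of the loss of Neil2, or of the unverified loss of Neil1, on the called genes stays open. It was not tested, as neither the strains nor the alleles are given in the sources used here.

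Plac9a, Tmem254a and Duxbl1 were higher in both knockouts on the contralateral side. With separate wild-type libraries for each knockout, 2 of the 3 genes were still called in both under the less favourable assignment. These calls thus did not need a wild-type library used for both knockouts. The 3 genes were picked with all of these libraries, so the split cannot exclude chance values of the shared wild-type libraries. Sex is argued against, since among animals with low Xist 2 of the 3, Tmem254a and Plac9a, were called in both. A colony or strain difference of the wild-type animals may account for the pattern and cannot be told apart from an effect of the knockouts: the knockouts differed from each other by a median of 0.398 (log2) over these genes, more than the SE of 0.178 and less than their median absolute difference from wild type of 1.31. All 3 genes lie on the chromosome of Neil2 in assembly GRCm38.p6, and the counting of their near-identical copies adds to what stays open.

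Other splits of the compared libraries were refitted on those libraries alone, so the real values differ from the counts above. For labelled Neil1-KO against wild type on the contralateral side 2 of 35 splits, the real split included, gave at least as many calls (real 32, highest other 74). This share alone could not exclude chance. The same held on the ipsilateral side (2 of 35; real 7, highest other 22), and for Neil2-KO against wild type contralaterally (3 of 35; real 9, highest other 117) and ipsilaterally (3 of 35; real 8, highest other 1524). Among the 18 splits with both times equally in each group, too few for a share under 0.05, the highest other was 74 for labelled Neil1-KO contralaterally and 0 in the 3 other comparisons. The highest contralateral splits set the 4 libraries with Ttr above 10000 against the other 4, a structure of the samples in choroid plexus content, and the highest ipsilateral splits set 3 h against 6 h, a known difference of the samples. For labelled Neil1-KO no further split reached the real count, which limits what its share says about chance. Of the genes called besides the target, 47.4% (labelled Neil1-KO, contralateral), 85.7% and 84.2% (Neil2-KO, contralateral and ipsilateral) lay on the target's chromosome. Of the other tested genes 5.35%, 3.93% and 3.91% did. These shares argue against chance for the called genes on those chromosomes, with less weight than their counts imply. Neighbouring genes such as Tmem254a and Plac9a in Neil2-KO are not independent, so the shares rest on fewer blocks than genes. For the differences of side response all 35 of 35 splits reached the real value of 0, with highest others of 25 (labelled Neil1-KO against wild type), 394 (Neil2-KO against wild type, 3 h against 6 h) and 4 (between the knockouts). For the difference between times 1 of 100 drawn splits, the real one, gave as many calls (real 382, highest other 188). That share lay under the bound of 0.05 and argues against chance. Only 100 of 462 splits were drawn, so chance was not firmly excluded here. For the contralateral difference between times 3 of 100 did (real 31, highest other 97). This share lay under the bound of 0.05, but only 100 of 462 splits were drawn, so chance was not firmly excluded. The highest split gathered the libraries with high Ttr, again a structure in choroid plexus content.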

How the results depend on the processing

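All alternative analyses set in advance were run. The sex term, the animals with low Xist, the fit without the outlying library and the choroid plexus term were chosen after the data were seen. Counts of called genes stayed within 1.5 times the reported count in 192 results and moved further in 112. Gene list calls kept direction and side of the threshold in 1675, lost the call in 110 and turned in camera direction in 3. Named genes kept both in 2117, lost the call in 420 and changed sign in 9. TMM scaling, edgeR, a pseudocount of 5 and no filter moved no count by over 1.5 times. With fewer than 2 libraries left in a group, the lone library was assumed to vary like the other groups. The cause of the shifts below was not tested, except that fewer libraries and degrees of freedom enter the smaller fits.

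With only the compared groups in the fit the counts were 1946 (wild type sides, 3 h), 2509 (6 h), 1852 and 2685 (labelled Neil1-KO sides, 3 h and 6 h), 2790 (Neil2-KO sides, 3 h), 117 and 4 (labelled Neil1-KO against wild type, contralateral and ipsilateral), 9 (Neil2-KO against wild type, ipsilateral), 1 (Neil2-KO minus wild type side response; Metap1d, 0.983, named after its values were seen) and 228 (6 h against 3 h, contralateral). This setting does not apply to the difference of side response between times, which uses all groups. DESeq2 gave 1304 (wild type sides, 3 h), 84 (labelled Neil1-KO, contralateral), 37 and 38 (Neil2-KO, contralateral and ipsilateral), 5, 1 and 3 (differences of side response between genotypes), 798 (between times) and 268 (6 h against 3 h, contralateral). With a sex term the counts were 705 (labelled Neil1-KO, ipsilateral), 9 (Neil2-KO, contralateral) and 34 (6 h against 3 h, contralateral). With the choroid plexus term they were 1273 (wild type sides, 3 h), 225 (labelled Neil1-KO, ipsilateral), 9 (Neil2-KO, contralateral), 561 (difference between times) and 94 (6 h against 3 h, contralateral). Among animals with low Xist they were 1585 (wild type sides, 3 h), 2996 (labelled Neil1-KO sides, 6 h), 10 and 710 (labelled Neil1-KO, contralateral and ipsilateral), 4 (Neil2-KO, contralateral; Esd, Neil2, Tmem254a and Plac9a), 1 and 1 (side response of labelled Neil1-KO minus wild type, Trhr at -2.01, and of Neil2-KO minus labelled Neil1-KO, Htr2c at 1.21, both named after their values were seen), 24 (difference between times) and 9 (6 h against 3 h, contralateral). Without the outlying library they were 1636 (wild type sides, 3 h), 3991 (labelled Neil1-KO sides, 6 h), 2595 (Neil2-KO sides, 3 h), 31 and 345 (labelled Neil1-KO, contralateral and ipsilateral), 535 (difference between times) and 147 (6 h against 3 h, contralateral).

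With animal as a block, taking libraries of the sides with the same number as 1 animal, the counts were 776 and 3687 (wild type, 3 h and 6 h), 3067 and 7049 (labelled Neil1-KO), 1733 and 4513 (Neil2-KO), 0, 0 and 0 (differences between genotypes) and 370 (difference between times). Of the calls of lists and named genes, the block ended only that of Ipp in the difference between times. With replicate number as a block, where the animals share only a number, the counts were 22 and 1476 (labelled Neil1-KO against wild type, contralateral and ipsilateral), 12 and 19 (Neil2-KO) and 54 (6 h against 3 h, contralateral).

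Leaving out each library gave 155 to 612 calls for the sides in wild type at 3 h and 1574 to 3396 at 6 h, 1231 to 3152 and 3991 to 8116 in labelled Neil1-KO, and 289 to 963 and 2074 to 3978 in Neil2-KO. It gave 15 to 33 and 95 to 5246 for labelled Neil1-KO against wild type (contralateral, ipsilateral), 3 to 127 and 10 to 364 for Neil2-KO, 0 to 2101, 0 to 50 and 0 to 801 for the differences between genotypes (labelled Neil1-KO minus wild type, Neil2-KO minus wild type, Neil2-KO minus labelled Neil1-KO), 63 to 1405 for the difference between times and 4 to 57 for 6 h against 3 h. The genes whose sign changed were not called under any setting. Without each library in turn, Neil2 in labelled Neil1-KO against wild type, contralateral, ranged from -0.0894 to 0.2277, and was -0.0894, -0.00852 and -0.0575 without wild type 3 h replicate 1, labelled Neil1-KO 3 h replicate 1 and labelled Neil1-KO 6 h replicate 2. Neil1 in Neil2-KO against wild type ranged from -0.2395 to 0.0333 contralaterally and from -0.0273 to 0.1466 ipsilaterally, and was 0.0333, 0.00691 and 0.0142 contralaterally (without wild type 6 h replicate 2, Neil2-KO 3 h replicate 1 and 6 h replicate 2; also 0.0142 among animals with low Xist) and -0.0273 and -0.00597 ipsilaterally (without wild type 6 h replicate 1 and Neil2-KO 6 h replicate 1). The direction of the preset camera test turned, and its call ended, for 3 lists: microglia markers in labelled Neil1-KO against wild type, ipsilateral, without the outlying library (median -0.0611, 0.27 with it), choroid plexus markers in Neil2-KO against wild type, contralateral, with the choroid plexus term (median -0.0610, -1.32 without it), and astrocyte markers in the side response of Neil2-KO minus labelled Neil1-KO without the outlying library (median -0.00494, -0.18 with it). Neil2 rested on few reads, with 15.15 to 27.78 normalized counts per wild-type library.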

Other observations

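The planned comparisons also hold gene groups not described in the report; the levels per library of Ttr and Hba-a1 were singled out after the data were seen. Base excision repair genes, the pathway of Neil1 and Neil2, had 3 higher and 2 lower of 24 members between the sides in wild type at 6 h, the same counts adjusted over the list alone (camera adjusted p = 0.79). Parp1, which senses DNA breaks, fell (-0.60 ± 0.13, SE, limma adjusted p = 0.00388) with the glycosylase gene Tdg (-0.36), while the glycosylase gene Ung (0.64) and the ligase gene Lig1 (0.55) rose. At 3 h 0 of the 24 were called by limma, also 0 adjusted over the list alone. Parp1 also fell in labelled Neil1-KO at 6 h (-0.80), and Neil3 was higher in labelled Neil1-KO than in wild type ipsilaterally (0.83 ± 0.24, limma adjusted p = 0.0369), but was not called with only the compared groups in the fit. Hypoxia and HIF target genes rose for 2 of 19 at 3 h in wild type, Adm (2.08) and Egln3 (0.88), and at 6 h for 6 with 1 lower, the kinase gene Pdk1 (-0.32). Adjusted over the list alone 5 were higher and 1 lower at 3 h and 6 and 2 at 6 h, and the list was not called by camera (adjusted p = 0.166 and 0.174). Genes of the NRF2 and oxidative stress list rose for 6 of 16 at 6 h, including Hmox1, heme oxygenase (2.80), and Osgin1 (2.31), and Gclc fell (-0.39). The counts were the same adjusted over the list alone (camera adjusted p = 0.0434, and adjusted p = 0.265 with an estimated correlation). Genes of the combined p53 and apoptosis list rose for 10 of 19, among them Gadd45b (2.98), and Hrk fell (-0.63). Adjusted over the list alone 11 were higher and 1 lower (camera adjusted p = 5.2e-06, and adjusted p = 0.139 with an estimated correlation).

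Cell type markers differed between the sides as well. Endothelial markers rose for 10 of 11 in labelled Neil1-KO at 6 h, also 10 adjusted over the list alone (camera adjusted p = 3.46e-05, and adjusted p = 0.262 with an estimated correlation). Hba-a1, a hemoglobin gene, was 6319 and 14000 normalized counts in these ipsilateral libraries, the second being the outlying library, and 3462 and 4262 contralaterally. Interferon response genes rose for 14 of 18 in labelled Neil1-KO at 6 h (15 adjusted over the list alone; camera adjusted p = 1.44e-07, and adjusted p = 0.109 with an estimated correlation) and, with no test of the difference at 6 h, for 6 in wild type (6 adjusted over the list alone; camera adjusted p = 0.00259, and adjusted p = 0.295 with an estimated correlation), among them Rsad2 (2.17) and Gbp2 (2.29). The microglial homeostatic genes P2ry12 (-1.88) and Tmem119 (-1.42) fell in wild type at 6 h while Fcrls (1.31) rose, with 2 of 12 microglia markers higher and 2 lower, the same adjusted over the list alone.

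The libraries with Ttr above 10000 normalized counts were, contralaterally, wild type 3 h replicate 1 (35650), wild type 6 h replicates 1 and 2 (30930 and 27740), labelled Neil1-KO 3 h replicate 1 (29290) and Neil2-KO 6 h replicate 1 (29070), and, ipsilaterally, labelled Neil1-KO 6 h replicates 1 and 2 (11310 and 19800) and Neil2-KO 3 h replicate 2 (26780). Among the 5068 unnamed genes that passed the filter on low values, limma called 74 and 263 between the sides in wild type at 3 h and 6 h, 154 and 682 in labelled Neil1-KO and 104 and 333 in Neil2-KO.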
